A study of Mus musculus with 18 samples.

How the data were processed

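The series compared DNA of 9 mice of 1 family with DNA of 1 reference male on 18 two-colour oligonucleotide arrays. Each mouse was hybridised on 2 arrays with exchanged dyes, and these 2 arrays entered every test as 1 replicate. Mice were assigned to the groups sire (1), dam (1) and F1 progeny (7) from the channel labels. The labels do not agree on the number of the reference mouse, and they disagree on whether the sire was irradiated, as the title and the protocol have it exposed while 1 sentence of the design text does not. These arrays are the primary screen of a study that went on to denser arrays and quantitative PCR, which were not analysed here.

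Per the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction 12.1.0.3, which gave processed signal intensity values per spot after background subtraction, detrending and linear dye normalization, with no lowess factor. The deposited log10 ratio column holds red over green from the same signals and was used as a check. The authors' value table was deposited as log2 ratios; against the scanner values its 18 columns had correlations near -1 with log2(mouse/reference), so it holds reference over mouse, and its column medians lay between -0.0033 and 0.0148, so it was near-centred. Its software and smoothing are not given in the sources used here. No per-sample column of that table was left unused. Median spot and background intensity values, deposited in the same files, were used for the normexp alternative. Probe positions are those of the array design on mm9 (NCBI37), per the file headers.

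The log2 ratio of mouse over reference was taken from the processed signals, spots of 1 probe were averaged, and each array was centred on the median of its autosomal probes. No loess or quantile step was applied. Control spots and probes with an outlier flag on any array were left out (13951 autosomal probes), which kept 936671 autosomal, 28 X and 20 Y probes, while dim and saturated spots were kept. The 2 arrays of a mouse were averaged. Between mice, arrays of the same dye orientation correlated with r from 0.286 to 0.571 over all probes, and the 2 arrays of a mouse, both turned to mouse over reference, with r from -0.427 to -0.306. This dye effect of the probes cancels in the swap mean, and swap means of different mice had r from -0.167 to 0.246. No arrays were identical. The number of arrays limits the precision.

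Segments were found by a recursive search of each chromosome for the interval with the largest absolute sum over its noise, as in the ADM method of Agilent, with a score of 6 or more, 3 probes or more, an absolute mean of 0.25 or more, and the same sign with 0.125 or more on each array. The noise was the derivative spread of the mouse. False calls were estimated by the same search on the dye-swap half-differences, after the mean half-difference of each probe was removed. This estimate holds array noise but not effects shared by the arrays of a mouse, whether peculiar to it or recurring in other mice. It is therefore a lower bound. The search was tested on simulated data, with segments placed in the half-difference noise of the 9 mice over 936671 probes. It found 99.2% of 3-probe segments at -0.5, 73.3% at 0.3, and 91.1% of 5-probe segments at 0.3. Segments of any mice that shared a probe were joined into regions, and the core is the set of probes covered by the most segments. A region was placed in F1 progeny alone when neither parent was called and both parents' core means were under 50% of the caller's. Regions that met no class were 24 called in both directions and 74 in F1 mice with an unclear parent.

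Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the swap means, Benjamini-Hochberg adjustment), for F1 progeny against 0 and for F1 progeny against parents. The prior variance followed the mean brightness of the probes. A first version let it follow the mean log ratio, which is the tested value itself; it called 0 probes against the reference, and it was replaced after that count had been seen. On simulated data limma recovered 100% of 100 probes changed by 0.5 and called 3 unchanged probes in the comparison with the reference and 0 in that with the parents. The simulated noise was normal, independent between mice and with 1 spread per mouse for all probes. It therefore does not give the recovery for real probes, whose spreads differ. Chromosome means were tested by an exact sign-flip permutation test and transmission by an exact binomial test. Scan batches (5, each of 1 or 2 mice) were read from the file headers and used as a random block with statmod 1.5.0. The parents shared 1 batch that held no F1 mouse, so the block cannot separate batch from group in the comparison with the parents. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

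Apart from the brightness trend of the prior variance, the tests and most alternatives were fixed before the data were examined. So was the rule for named regions: the 10 highest scores among regions in F1 progeny alone and among regions in a parent and F1 progeny, the 5 highest among regions in all 9 mice and the 5 highest among regions in a parent alone. The shared part and the sire's part of the chromosome 14 region were set apart after their values were seen. Alternatives covered normexp background correction (offset 50), which used median signals because the files hold no mean signals, the authors' value table, probe filters, centring, score, size and probe limits, single dye orientations, each F1 mouse left out and the scan batch. The gene lists, the named genes and the marker loci between flanking genes were planned and not run, because the arrays carry no gene names, the supplied gene table is of the GRCm38 build, and positions were not converted between builds.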

Results

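Copy number was measured along the 19 autosomes of 9 mice of 1 family by array comparative genomic hybridisation, in which DNA of a test mouse and of a reference are labelled with different dyes and compete for the same probes. The mice were a sire, an unexposed dam and 7 of their F1 offspring. The series title gives the sire's exposure as gamma rays at 0.05 mGy per day for 400 days, although 1 sentence of the design text calls this male non-irradiated. Tail DNA of each C57BL/6JNrs mouse was set against DNA of 1 reference male of the same colony on 2 arrays with exchanged dyes, which counted as 1 replicate. The arrays held 950622 autosomal probes with a median spacing of 2053 bp, together with 68 X and 23 Y probes. Median background-subtracted signals per channel were 92.1 to 474 intensity units, lowest in F1-7 (92.1 to 160). The spread between neighbouring probes was 0.127 to 0.202 on the log2 scale per array. All ratios are log2(mouse/reference), so negative values stand for less DNA in the mouse; the authors' value table has the opposite sign. Positions are on the mm9 build, and the files give no gene names. Because no family of an unexposed male was used here, none of the values measures an effect of radiation.

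The first question was whether offspring carried copy number changes that neither parent had. F1-1 had 2 such losses, with scores of 42.8 and 18, where the dye-swap half-differences, which hold no copy number signal, reached at most 14.2 in any mouse. On chromosome 14, from 87131579 to 87188326, 33 consecutive probes averaged -0.49 (SE over probes 0.016) in F1-1, with -0.51 on the array with F1-1 in Cy3 and -0.47 on the array with F1-1 in Cy5. The other 8 mice lay between -0.03 and 0.007 over the same probes. On chromosome 8, from 14436415 to 14449986, 6 probes averaged -0.48 (SE 0.016) in F1-1, with -0.57 and -0.40 on its arrays, while the other 8 mice lay between -0.052 and 0.023. Both losses were about as deep as each other, and both were shallower than the loss on chromosome 10 that F1-1 shared with its sire (-0.99, SE 0.006, 2 probes). No replicate error can be given for a change seen in 1 mouse, so the errors are over probes.

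**Figure D1:**
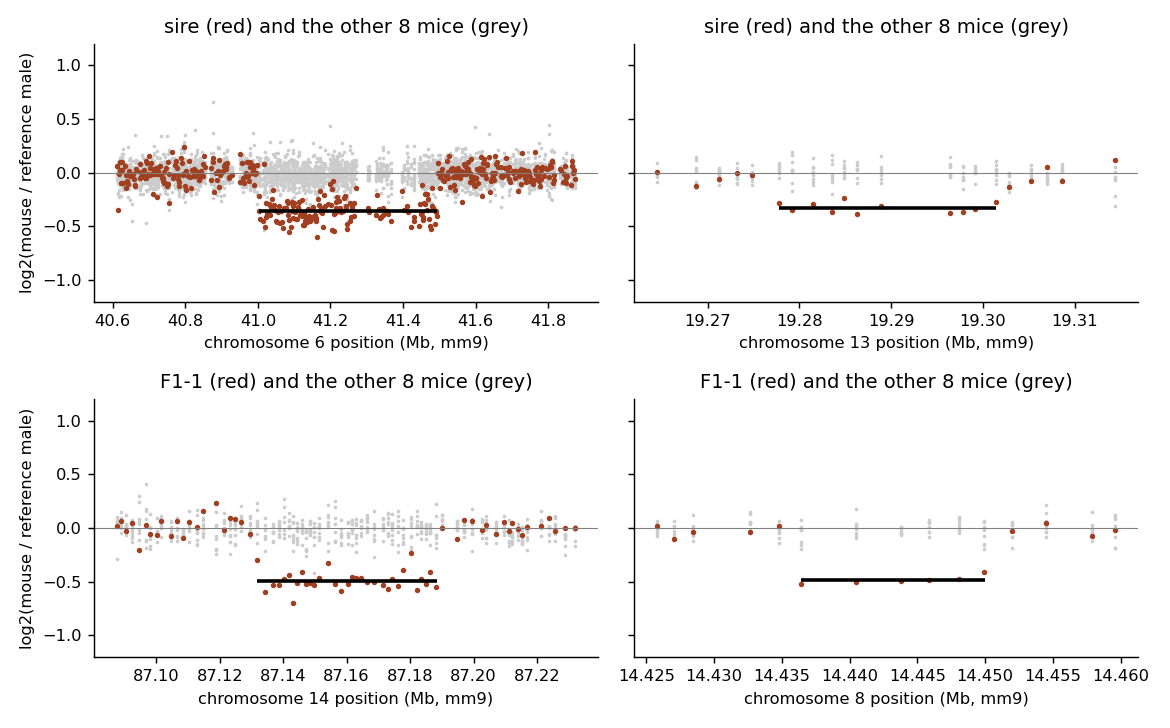
Log2(mouse/reference male) per probe against position in Mb along chromosomes 6 and 13 around losses of the sire, and along chromosomes 14 and 8 around losses of F1-1. Red points are the mouse named in the panel title, grey points the other 8 mice, which scatter around 0 with single points below the line on chromosome 6, and black lines the segment means of -0.35, -0.33, -0.49 and -0.48.

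In all, 378 regions were called in F1 progeny alone, 162 higher and 216 lower than the reference, and 364 of them in 1 mouse. The same search on the half-differences gave 140. Of the 378 regions, 9 held a segment of 5 probes or more, against 4 from the half-differences. The other 8 named regions, on chromosomes 1, 2, 3, 10, 11 and 13, rested on 3 or 4 probes with scores of 10.6 to 13.1, all below the 14.2 that the half-differences reached. With normexp signals all 8 lost their call, and without dim and saturated probes 6 of the 8 did. Examples were a mean of 0.56 in F1-2 at chromosome 10, 105149354 to 105154927 (SE over 3 probes 0.53), which stayed at 0.49 with normexp and was still called without dim and saturated probes, and of 0.71 in F1-7 at chromosome 3, 57048171 to 57052461 (SE 0.56), which fell to 0.11 with normexp and to 0.16 without dim and saturated probes. Their errors over probes were nearly as large as their means, unlike those of the F1-1 losses. The count fell to 62 with at least 5 probes (31 from the half-differences), to 58 at a mean of 0.4 or more (53 from the half-differences) and to 5 when each array had to give the call by itself. The 62 came from a new search with that limit, which can draw wider intervals, and are not the 9 regions above.

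Regions shared by a parent and offspring numbered 40, against 2 from the half-differences. Of the 40, 15 were called in the sire and 25 in the dam. In 23 of them only 1 F1 mouse was called, and 12 had a core of 1 probe. The half-differences had each probe's mean over the mice removed and do not hold effects that recur between mice in the swap means. The 2 is therefore no estimate of shared regions that come from such effects. The count of 40 fell to 22 with normexp signals, to 16 at score 8 and to 6 when each array was searched alone. A loss at chromosome 10, 8065864 to 8071834, was found in the sire (-0.94, SE 0.038), F1-1 (-0.99, SE 0.006), F1-3 (-0.98, SE 0.0051) and F1-6 (-0.97, SE 0.17) over the 2 probes that all calls covered. The dam, F1-2, F1-4, F1-5 and F1-7 lay between -0.16 and 0.052 there. A gain at chromosome 13, 95703166 to 95712034, was called in the sire and in F1-1 to F1-6, and it rested on the 1 probe at 95707465. That probe read 2.79 in the sire and 1.36 to 2.02 in F1-1 to F1-6, but -0.03 in the dam and -0.14 in F1-7. A loss at chromosome 14, 93190051 to 93212291, was called in the dam, F1-2 and F1-4, where its single shared probe read -1.11, -0.62 and -1.24. That probe also read -1.97 in F1-5, where the region was not called. The F1-4 segment there averaged -0.50, and -0.26 with normexp signals. It lost its call with normexp signals and when each array was searched alone.

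Another 7 of the 10 named shared regions were each called in the dam, F1-4, F1-5 and F1-6 and in no other mouse. A 3-probe loss at chromosome 3, 25417435 to 25432738, averaged -1.73, -1.75, -1.65 and -1.66 in these mice, and between -0.015 and 0.067 in the others. At chromosome 8, 102132083 to 102257578, the 27 shared probes averaged 0.27, 0.26, 0.30 and 0.25, each with an SE of 0.034 or less. The sire had an intermediate 0.096 (SE 0.015) there, while F1-1, F1-2, F1-3 and F1-7 lay between -0.016 and 0.02. At chromosome 14, 61798066 to 61819370, the 11 shared probes averaged -0.29, -0.28, -0.26 and -0.27 in the dam, F1-4, F1-5 and F1-6, and -0.042 to 0.041 in the others. The losses at chromosome 5 (109215576 to 109223996 and 123592752 to 123603094) and chromosome 9 (35853071 to 35865189) each rested on 1 shared probe, and the loss at chromosome 6 (104238274 to 104242812) on 3 probes with SEs of 0.30 to 0.57. These are also the mice whose X probes read higher and whose Y probes read lower than the reference male, as given for the sex chromosomes. The 7 regions count among the shared regions called in the dam. Calls that follow the X and Y readings do not by themselves show that a change passed from the dam.

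Transmission was tested for the 133 regions called in 1 parent, with an exact two-sided binomial test of the number of the 7 F1 mice carrying each against an even chance. For 93 of the 133 no F1 mouse was called, which gives p = 0.0156 and an adjusted p of 0.0224 in the binomial test. No region was called in all 7. With 7 mice only 0 or 7 carriers can give p under 0.05 in this test. These 93 therefore passed by the rule that defines a region in a parent alone. Of the 96 regions called in a parent alone, 2 held a segment of 5 probes or more. The half-differences gave 51 parent-only regions, 0 of them with such a segment. For the shorter regions the result therefore does not show that changes failed to pass to the offspring. Some F1 mice without a call read as far from 0 as the parent. At chromosome 4, 137854898, F1-6 read 0.487 and the dam 0.407. At chromosome 3, 80635641, F1-5 and the dam both read -0.396. At chromosome 12, 82591869, the F1 mice read -0.117 to 0.215, against 0.434 in the sire. The 2 longer regions averaged -0.35 and -0.33 in the sire. An even chance presumes a change on 1 chromosome of the pair in every cell, which was not shown for them. The test was run with the main settings only, and the 96 fell to 22 with normexp signals. The chromosome 13 gain, carried by 6 of 7 mice, had an adjusted p of 0.142 in the exact test, and the chromosome 10 loss, carried by 3 of 7, one of 1.0.

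The widest change in the family lay on chromosome 14, from 53385238 to 54775992, over 279 probes. Its left part, 53387255 to 54386805, was lower than the reference in both parents and in 6 of the 7 offspring. Over 106 probes the mean was -0.52 (SE 0.032) in the sire, -0.50 (SE 0.023) in the dam and -0.48 to -0.43 in F1-1 to F1-6. F1-7 averaged 0.0043 (SE 0.025) there. Within that part F1-7 was called for a loss of 11 probes (-0.29, SE 0.12, score 9.05, 53961688 to 54073297). It was also called for a gain of 3 probes (0.59, score 9.58, 54251955 to 54278038). Both scores lay below the 9.59 that the half-differences reached in F1-7. The gain read 0.915 and 0.272 on the 2 arrays of F1-7, and F1-1 was called lower at the same probes (-0.418). The region was the 1 region called lower in all 9 mice, but that call rested on 4 probes at 53961688 to 53984192, the only ones that the F1-7 loss shared with all others. Over these 4 probes the means were -0.24 (SE 0.17) in F1-7, -0.18 (SE 0.22) in F1-2 and -0.12 (SE 0.30) in F1-4. The other mice had -0.595 to -0.345, with SEs of 0.054 to 0.32. No region was called in all 9 mice with normexp signals, without dim and saturated probes, with joining at 50% overlap or when each array was searched alone. Because every array used the same reference DNA, a gain in the reference male would give the same readings as a loss in the family.

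**Figure D2:**
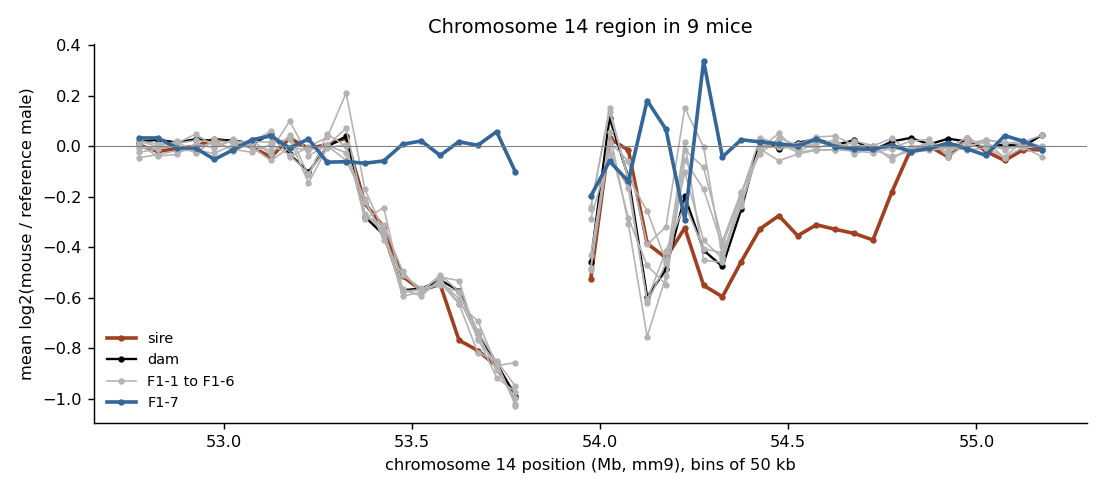
Mean log2(mouse/reference male) in bins of 50 kb against position in Mb along chromosome 14, 1 line per mouse, with breaks where no probe lies. The dam and F1-1 to F1-6 drop on the left of the region, the sire also stays near -0.33 on the right of it, and F1-7 averages 0.0043 over the shared part.

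The sire had 3 losses of 5 probes or more, each of them wholly or partly seen in no other mouse, and all of about the same depth there. On chromosome 6, from 41002588 to 41492582, 155 probes averaged -0.35 (SE 0.008), with -0.33 and -0.37 on its arrays. On chromosome 13, from 19277746 to 19301474, 11 probes averaged -0.33 (SE 0.015), with -0.28 and -0.38 on its arrays. The score of this loss, 13.5, lay below the 14.2 that the half-differences reached in any mouse and near the 13.2 they reached in the sire. The half-differences gave 0 segments of 10 probes or more. On chromosome 14 the sire's loss ran on to the right of the shared part, from 54391011 to 54775992, where 169 probes averaged -0.33 (SE 0.01). The other 8 mice lay between -0.031 and 0.004 on chromosome 6, between -0.033 and 0.06 on chromosome 13 and between -0.024 and 0.019 on chromosome 14. None of the 7 offspring carried the chromosome 6 or chromosome 13 loss. The chromosome 6 loss was flat, at -0.36, -0.35 and -0.35 over its left, middle and right parts (SE 0.015 or less). Chromosomes 6, 13 and 14 carry the T cell receptor beta, gamma and alpha/delta loci, which lose DNA when T cells rearrange them. Whether the segments lie in these loci was not settled, because no annotation of the mm9 build was used here. In total 96 regions were called in a parent alone, against 51 from the half-differences. The count was 22 with normexp signals, 16 at score 8 and 3 when each array was searched alone. The other 3 named ones, on chromosomes 3, 4 and 12, were 3-probe calls with scores of 9.41 to 9.75, also below 14.2. The chromosome 6 and 13 losses were not called at a minimum of 0.4, and the chromosome 13 loss also not with normexp signals or when each array was searched alone.

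The sex chromosomes set the dyes and labels against known differences. In the dam, the 28 X probes kept averaged 0.92 (SE 0.024) and the 20 Y probes -2.44 (SE 0.29), as for a mouse with an added X and no Y relative to the reference male. F1-4, F1-5 and F1-6 gave 0.91, 0.92 and 0.92 on X and -2.57, -2.62 and -2.54 on Y. F1-1, F1-2, F1-3 and F1-7 gave -0.03 to 0.025 on X and -0.044 to 0.069 on Y. The sire fell between these on X, at 0.28 (SE 0.015), with all 28 probes above 0 and with 0.33 and 0.22 on its arrays. Its Y probes averaged 0.018 (SE 0.023). With normexp signals the sire's X mean was 0.15 and that of the dam 0.75.

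**Figure D3:**
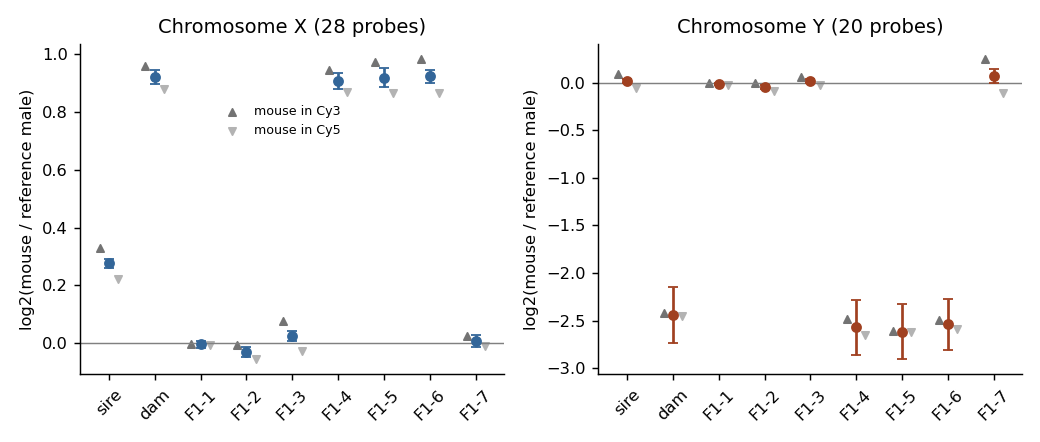
Mean log2(mouse/reference male) over the X probes (left) and Y probes (right) for each of the 9 mice. Circles are dye-swap means with the SE over probes and triangles the single arrays; the sire's X mean of 0.28 lies between the values near 0 and those near 0.92.

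No whole autosome was gained or lost. The 171 autosome means of the 9 mice lay between -0.0091 and 0.0056. Over the 7 offspring, the exact two-sided sign-flip permutation test found 0 of 19 autosomes past an adjusted p of 0.05 and 0 at an unadjusted p under 0.05. The smallest adjusted p over the 21 chromosomes was 0.656, and p = 0.0156 was the smallest the test can give with 7 mice. With only the arrays that had the mouse in Cy5, 16 chromosomes passed, and with only those that had it in Cy3, 0 did.

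Segments were counted per mouse to place these regions against the noise. The 9 mice gave 770 segments, 370 higher and 400 lower, and the half-differences gave 258. The sire had 69, the dam 86 and the F1 mice 87.9 ± 39.0 (SD, n = 7), from 48 in F1-3 to 162 in F1-4. Segments of 3 or 4 probes made up 738 of the total. Of the 32 segments of 5 probes or more, against 4 from the half-differences, most lay on chromosome 14 and in the chromosome 8 region of the dam, F1-4, F1-5 and F1-6. Of 10 probes or more there were 22 segments, against 0. The total fell to 358 with normexp signals, to 164 with at least 5 probes and to 37 when each array was searched alone. The limit of 5 probes was set in a new search, which can draw wider intervals. The 164 are therefore not the 32 above.

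**Figure D4:**
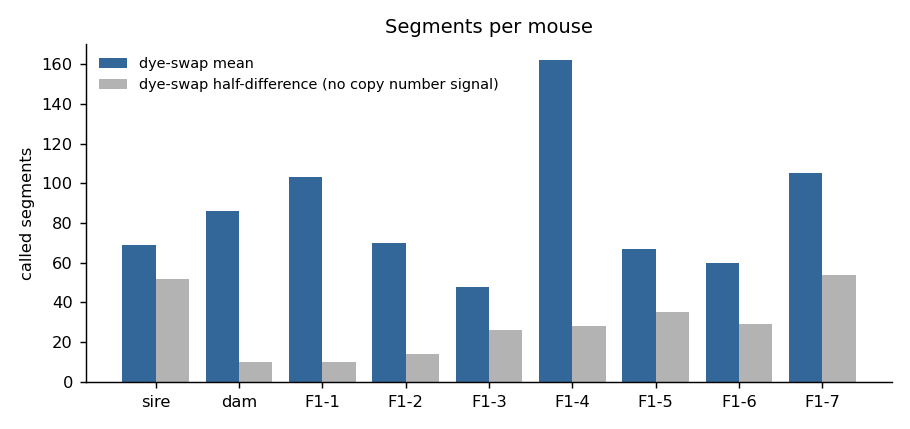
Number of called segments per mouse in the dye-swap mean (blue) and in the dye-swap half-difference (grey), which holds no copy number signal. Blue bars run from 48 to 162 and grey bars from 10 to 54.

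Probe by probe, the offspring differed from the reference male mainly in the chromosome 14 region. With limma, 104 of 936671 probes passed an adjusted p of 0.05 over the 7 F1 mice, 13 higher and 91 lower. Of these, 77 lay in the chromosome 14 region, all lower, with means down to -0.90. The other 27 were spread over 14 autosomes, and 23 of them had means within 0.25 of 0. The reference was 1 animal, so its own spread does not enter this test. The count was 169 without F1-7, 5 without a trend in the prior variance and 0 with that trend taken over the mean log ratio.

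Between offspring and parents, limma found 0 probes past an adjusted p of 0.05 (29742 at an unadjusted p under 0.05), in a comparison of 7 mice with 1 sire and 1 dam. The parents shared 1 scan batch that held no F1 mouse, so group and scan batch cannot be told apart here. No probe of the sire's losses on chromosomes 6 and 13 passed, and the dam did not have these losses. A probe with a difference of -0.59 (SE 0.14, chromosome 14 at 21695271) did not pass either. The 0 therefore does not show that differences of this size are absent.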

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

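All tests of explanations in this part, and the comparison of other choices of 2 mice among them, had their criteria written after the result was seen. Over the 7 F1 mice, 53 sets of values were searched for a mouse far from the rest by Dixon's ratio at its 95% critical value, and 17 had one; chance alone gives about 1 in 20 sets, or 2.7. Regions called in 1 F1 mouse stand apart by construction. F1-1 did so with the losses on chromosome 14 (-0.49, next -0.027) and chromosome 8 (-0.48, next -0.043). F1-2 did so at chromosome 10 (0.56) and chromosome 11 (0.46), and F1-5 at chromosome 2 (0.66) and chromosome 1 (0.60). F1-7 did so at chromosome 3 (0.71) and on chromosome 10 at 129975769 (0.57) and 34111429 (-0.66). With normexp signals none of these regions of F1-2, F1-5 and F1-7 was called, although F1-2 at chromosome 10 kept a mean of 0.49. The means were 0.11 at chromosome 11, 0.034 at chromosome 2, 0.021 at chromosome 1, 0.11 at chromosome 3, and 0.055 and -0.079 at the 2 chromosome 10 regions of F1-7. F1-4 had 113 segments higher than the reference, where the next mouse had 46. F1-2 had the lowest means of chromosomes 2 (-0.007), 6 (-0.007), 10 (-0.006), 12 (-0.008) and 18 (-0.006), where the next-lowest F1 means lay between -0.003 and 0.001. F1-7 was the 1 F1 mouse without the chromosome 13 gain (-0.139, next 1.36) and without the shared chromosome 14 loss (0.004, next -0.432).

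The sire combined an X mean of 0.28 with losses on chromosomes 6, 13 and 14. DNA of a mouse with 2 X and no Y mixed into the sire's would have lowered its Y mean to -0.25, and the observed value was 0.018 (SE 0.023), which argues against it. If some cells had an added X and lacked both copies of each lost segment, their share can be read from each. It would be 21.1% from X, 21.7% from chromosome 6, 20.2% from chromosome 13 and 20.6% from chromosome 14. These shares differ by at most 1.62 SE, where the SEs are over probes and leave out differences between arrays. With normexp signals X gives 10.6% and the largest difference is 4.77 SE, so this stays open. Lymphoid cells with rearranged antigen receptor loci are another candidate explanation, since both losses in regions of the sire alone, on 6 and 13, lay on the 4 chromosomes of the loci listed before the data were examined (6, 12, 13 and 14), for which the chance by probe share is 0.0417, but rearrangement of autosomal loci leaves the X mean of 0.276 (SE 0.015) unexplained. The chance test leaves out the chromosome 14 loss, which overlaps the family's change, and places losses on chromosomes only. Of its losses, that on chromosome 13 had a score of 13.5, below the 14.2 that the half-differences reached. Positions within the loci, tissue makeup and the sire's exposure were not tested.

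The losses of F1-1 on chromosomes 14 and 8, at -0.49 and -0.48, were shallower than the -1 of 1 copy lost from 2. Compressed ratios on the F1-1 arrays are argued against by the chromosome 10 loss, whose 2 core probes averaged -0.994 on them (SE 0.006), although the called 3-probe segment averaged -0.66. Loss of 1 of 3 or 1 of 4 copies in every cell would give -0.58 or -0.42, or -0.54 or -0.38 when scaled by the dam's X mean of 0.92; the chromosome 14 loss lay 3.09 SE from the nearest of these, but 1.33 SE with normexp signals, so it stays open. Both losses may be carried by 1 share of the cells. They differed by 0.27 SE (1.11 SE with normexp), and that share would be 57.6% if 1 copy is lost. The SEs are over probes and leave out differences between arrays, such as -0.57 and -0.40 for the chromosome 8 loss. A small difference in these units therefore does not show a common share. No biological explanation that the groups define was tested.

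F1-7 lacked the changes on chromosomes 13 and 14 that the sire and F1-1 to F1-6 had. On chromosome 14 the dam had the change as well (-0.50, sire -0.52), so F1-7 differed from both parents there. The predictions on parentage used the chromosome 13 probe alone. Weak signal on its arrays is no sufficient account, because its mean over the 106 probes of the shared chromosome 14 part was 0.0043 (SE 0.025). F1-5 had -0.43 there, with signals of 124 and 172 intensity units on its Cy3 array and 218 and 276 on its Cy5 array. It is no matched control for F1-7, whose arrays had 92.1 to 160. A sire with the chromosome 13 gain on 1 chromosome of the pair would give carriers about its own excess over the reference, and the highest of the 6 carriers reached 0.52 of it. A sire with the gain on both chromosomes would give 0.5 and leave no offspring without it, so that F1-7 DNA could come from a mouse outside this family; the carriers' mean was 0.359 (SD 0.10), which lies below both predictions and rests on 1 probe, so this stays open. By calls, F1-7 carried 4 of all 40 shared regions. F1-1, F1-2 and F1-3, which like F1-7 read near 0 on X and Y, carried 8, 6 and 8, and F1-4, F1-5 and F1-6 carried 18, 12 and 13. Of the 10 named ones F1-7 carried 0, F1-1, F1-2 and F1-3 2 each, F1-4 and F1-6 9 and F1-5 8. The 7 called in the dam, F1-4, F1-5 and F1-6 alone went with the X and Y readings, so their absence from F1-7 does not bear on its family. The swap mean of F1-7 correlated with those of the other mice at r from -0.066 to 0.012, within the -0.167 to 0.246 of all pairs.

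Of the 36 choices of 2 mice out of 9 set against the rest with limma, all 36 gave as many probes as the real parents (0). With 0 real calls this holds by definition, so the count of choices decides nothing. The highest other choice was F1-4 and F1-6 with 5743 probes, which lie in different scan batches; no structure of the samples behind it was tested. Of the 4 pairs that share a scan batch, F1-1 and F1-2 gave 549, F1-5 and F1-6 gave 3, and F1-3 with F1-4 and the parents gave 0 each.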

How the results depend on the processing

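Alternatives chosen after seeing the data were the joint limit of score 8 and 5 probes, the probe median and leaving out F1-5 and F1-7. The prior trend over the mean log ratio was run first. The brightness trend of the report was chosen in its place after that version had called 0 probes against the reference. Counts of segments, regions in F1 progeny alone and regions in a parent and F1 progeny, in this order, were 770, 378 and 40. They were 358, 186 and 22 with normexp; 191, 56 and 16 at score 8; 164, 62 and 14 with at least 5 probes; 164, 58 and 10 at a mean of 0.4; 37, 5 and 6 with each array searched alone; 85, 19 and 9 at score 8 with 5 probes; and 223, 111 and 7 when the probe median also had to reach 0.25. At score 5 there were 1266 segments and 731 regions in F1 progeny alone. The half-differences gave 140 regions in F1 progeny alone against the 378, 405 at score 5, 24 at score 8, 31 with at least 5 probes, 53 at a mean of 0.4, 9 at score 8 with 5 probes and 31 with the probe median, so the excess over noise was smallest, as a ratio, at 0.4 (58 against 53). The 1 region in all 9 mice became 0 with normexp, without dim and saturated probes, with each array alone, at 50% overlap and with the probe median. Stricter limits lower the counts by construction, and the cause of the others was not tested. The limit of 5 probes was applied in a new search, so its 164 segments are not a subset of the 770. Leaving out 1 F1 mouse gave 291 to 361 regions in F1 progeny alone, 35 to 40 in a parent and F1 progeny and 1 in all. Probes against the reference (104) numbered 360550 with only Cy5 and 278117 with only Cy3, where the dye effect of the probes no longer cancels, 5 without a trend, 0 with the trend over the mean log ratio, the version run first, and 85 to 169 with 1 F1 mouse left out. Against the parents limma found 0 in every setting run (29742 at an unadjusted p under 0.05 with the settings of the report). With only Cy5, 16 chromosomes passed. Of the 26 named regions, 5 were called under all 14 settings tried on them, and 1 changed sign, the F1-7 gain at chromosome 10, 129975769, which read -0.008 without dim and saturated probes. The scan batch as a random block gave 109 probes against the reference and 0 chromosomes. Gene lists were not run. F1-7 had the weakest median background-subtracted signal (92.1 to 160 intensity units).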

Other observations

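The values in this part were chosen after they were seen. At the 7 named autosomal regions that were called in the dam, F1-4, F1-5 and F1-6, the sire read 0.096 at the gain on chromosome 8. At the 6 losses it read 0.063 on chromosome 3, 0.045 and -0.145 on chromosome 5 (109220847 and 123598779), 0.035 on chromosome 6, -0.08 on chromosome 9 and 0.041 on chromosome 14. The right part of the sire's chromosome 14 loss read -0.31, -0.32 and -0.36 from left to right (SE 0.025 or less).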
